A study of Homo sapiens with 66 samples.

How the data were processed

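Poly(A) RNA of A375 cells (ATCC; DMEM with 10% serum) was extracted with the RNeasy Plus Mini kit and made into KAPA Stranded mRNA-Seq libraries, per the labels' protocols. The deposited tables hold counts of reads per gene for 66 libraries in 3 tables, 1 per experiment, with 58721 Ensembl gene IDs each. Per the submitters' processing notes, reads were converted with bcl2fastq, aligned to hg38 with HISAT2 and counted with HTSeq. Versions, the gene annotation, the strand setting of the counting and the way of counting reads that map to several places are not given in the sources used here. Genes that overlap another on the opposite strand, or that have near-identical copies, therefore have uncertain counts. The values were checked to be whole numbers with a different total in every column. All 66 columns were mapped to samples, 15 of them under a name that is not the sample title. Of these, the 3 control columns of the HDAC3 table are named for GFP and were taken as that experiment's control samples by elimination, on which all comparisons with its control cells rest.

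Groups, comparisons, alternatives and the rule for naming genes were written before the data were examined. Each of the 22 groups has 3 replicates; doses were 1 µM vemurafenib or DMSO for 24 h. Gene IDs were matched to GENCODE 29 (58676 IDs) and to current symbols (58207 IDs), and coordinates are on GRCh38. Each experiment was fitted separately with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr on the design (minimum count 10, minimum total 15), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted. Contrasts weighted both guides equally, and interactions were differences between contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a 2-fold change; a named gene or list member is said to have risen or fallen at an adjusted p under 0.05 alone. SE is the absolute log2 fold change divided by the square root of F. Levels (CPM) are counts divided by the TMM-scaled library size in M.

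A total of 21 gene lists with 345 members were written from general knowledge at the same time: melanocytic lineage, neural crest and SOX10-associated, dedifferentiated and invasive, ERK pathway output, immediate early, receptor tyrosine kinase, YAP/TEAD, extracellular matrix and TGF-beta, cell cycle, lipid synthesis, interferon, antigen presentation, p53, stress response, lysosome and autophagy, Mediator, HDAC3 corepressor, neuronal, epithelial, blood cell and mitochondrial genes. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with the correlation estimated from the data. These p-values were adjusted over the 21 lists within a comparison. The genes called lower or higher in MED23 knockout cells in DMSO formed 2 further lists, with p-values adjusted over their 14 tests.

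Named genes were the targets (MED12, MED19, MED23, SOX10, HDAC3), 11 genes set beforehand (SOX10, MITF, MLANA, ERBB3, NGFR, AXL, EGFR, DUSP6, SPRY4, CCND1, MKI67), and the 5 highest and 5 lowest log2 fold changes of a comparison. The last had to have an adjusted p under 0.05, a symbol, a mean log2 CPM of at least 2 and no overlap between the libraries compared, and both guides alone had to pass with the same sign. A no-overlap criterion does not apply to interactions. Up to 4 members with the largest change were named per described list, with members that moved against it. Only some of the genes that the rule selects are reported here. Genes with under 30 counts over the 3 libraries of a group are given without a fold, apart from 1 whose direction reversed.

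Alternatives were no fold minimum, each guide alone, no low-count filter, DESeq2 size factors, a replicate block, only the groups compared, the Wald test of DESeq2 1.42.0, an estimated correlation, and leaving out each replicate. Whether replicate numbers pair libraries was checked by correlating deviations from group means: the mean over pairs with the same number was 0.005, 0.039 and 0.207 in the 3 experiments. Only HDAC3 knockout in MED23 knockout cells had every pair above 0.1 (0.129 to 0.333). Over the whole HDAC3 experiment 72.2% of the pairs with the same number were above 0.1, so its other comparisons may be paired in part. The replicate block is therefore reported for this experiment in the closing section. Counts of replicate libraries differed by 4.01 to 20.93 times the Poisson variance in the first experiment, by 1.42 to 5.8 in the second and by 4.16 to 17.28 in the third.

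The procedure was tested on simulated data made from the control means, library sizes and fitted dispersions of 3 comparisons. Genes to be changed were drawn only from those with a mean log2 CPM above 2, so recovery at lower levels was not tested. All 98 or 100 genes changed 2-fold, and all changed 1.5-fold, were recovered in each, and 11, 17 and 18 of 23989, 16925 and 20361 unchanged genes had an adjusted p under 0.05. These totals include unchanged genes that the low-count filter then left untested, since 23185, 16856 and 19969 genes were tested in all. With the 2-fold minimum 5, 3 and 5 unchanged genes were called. Simulated overlaps of knockouts with a shared control came from 5 runs. Depth lay between 24.87 and 211.79 M counts per library, and the 10 most abundant genes held between 3.34% and 5.71% of counts. At a few counts per library, values of single genes rest on too few reads for a fold.

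Not analysed here were protein levels, the reads themselves, splicing and the edited sites. Replicates are not stated to be separate cultures, and the SOX10 and HDAC3 experiments used a single MED23 knockout each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.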

Results

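RNA was sequenced from A375, a human melanoma cell line with mutant BRAF, after loss of single subunits of Mediator, the complex that links transcription factors to RNA polymerase II. The 66 libraries form 22 groups of 3 replicates in 3 experiments. In the first, 42 libraries came from cells with a control guide against GFP, or with 1 of 2 guides against MED12, MED19 or MED23, each treated for 24 h with DMSO or with 1 µM vemurafenib, an inhibitor of mutant BRAF. In the second, 12 libraries came from control or MED23 knockout cells that carried an empty vector or overexpressed SOX10, a transcription factor of the neural crest and melanocyte lineage. In the last, 12 libraries covered control cells, HDAC3 knockout, MED23 knockout and cells with both knockouts. HDAC3 is the deacetylase of the NCOR corepressor complex. Total counts per library lay between 65.88 and 211.79 M in the Mediator experiment (median 112.65), between 24.87 and 30.77 M in the SOX10 experiment (median 27.71) and between 58.84 and 106.19 M in the HDAC3 experiment (median 68.52). The labels do not say whether replicates were separate cultures, so every p-value below measures only the spread between libraries within groups. In the main fit each guide and treatment is a group of its own, so differences between the 2 guides of a subunit do not enter that spread. Gene values are log2 fold changes ± SE from edgeR's quasi-likelihood fit, with 3 libraries per group and both guides of a Mediator subunit weighted equally, and adjusted p-values are Benjamini-Hochberg values. Levels are in CPM, counts scaled by library size. Totals and overlaps of genes per comparison count those with an adjusted p under 0.05 and a 2-fold change, whereas single genes and members of gene lists are called higher or lower, risen or fallen, at an adjusted p under 0.05 alone.

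The guides were first read against the mRNA of the genes they target. MED12 (ENSG00000184634, chromosome X, 71118556 to 71142454, GRCh38), part of Mediator's kinase module, was at 28.7% of the control level in DMSO with guide 1 and at 20.5% with guide 2 (-2.04 ± 0.031, adjusted p = 1.9e-44 over both). MED19 (ENSG00000156603, chromosome 11, 57703714 to 57712323), of the middle module, was at 45.8% and 50.6% (-1.05 ± 0.043, adjusted p = 6.9e-26). MED23 (ENSG00000112282, chromosome 6, 131573966 to 131628229), of the tail module, was at 47.7% and 44.6% (-1.12 ± 0.033, adjusted p = 1.0e-31). The same guides left 25.4% and 18.3% of MED12, 48.2% and 54.8% of MED19, and 43.6% and 42.9% of MED23 under vemurafenib. MED23 also fell in the SOX10 experiment (-0.95 ± 0.055, adjusted p = 8.7e-15) and in the HDAC3 experiment (-1.07 ± 0.059, adjusted p = 2.8e-12). HDAC3 (ENSG00000171720, chromosome 5, 141620876 to 141636870) changed by -0.97 ± 0.05, adjusted p = 4.1e-13 in HDAC3 knockout cells and by -0.77 ± 0.05, adjusted p = 3.7e-11 when MED23 was lost as well. SOX10 (ENSG00000100146, chromosome 22, 37970686 to 37987422) rose by 0.19 ± 0.03, adjusted p = 7.5e-06 with the SOX10 vector in control cells and by 0.80 ± 0.03, adjusted p = 4.6e-19 in MED23 knockout cells. Whether reads from the vector entered the SOX10 counts could not be checked from the count tables, and mRNA levels do not measure the loss of protein.

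Vemurafenib in control cells gave the drug response against which the knockouts were read. All 18 measured ERK pathway output genes fell (18 adjusted over the list alone), with a median of -2.94. SPRY4, a feedback inhibitor of receptor signalling, changed by -6.56 ± 0.065, adjusted p = 7.0e-52, ETV4, an ERK-induced transcription factor, by -5.99 ± 0.06, and DUSP6, an ERK phosphatase, by -2.87 ± 0.042, adjusted p = 2.2e-45. All 21 cell cycle genes fell as well (21 adjusted over the list alone, median -2.75), with CCND1 at -3.77 ± 0.032 and the proliferation marker MKI67 at -3.21 ± 0.046. Pigment genes moved the other way: DCT, an enzyme of melanin synthesis, rose from 2.38 ± 0.253 to 848 ± 23.9 CPM (mean ± SD, n = 3; 8.49 ± 0.12, adjusted p = 4.2e-46), and MITF (ENSG00000187098, chromosome 3, 69739435 to 69968337), the lineage's master regulator, rose by 1.05 ± 0.035, adjusted p = 1.8e-30. Of 16 melanocytic lineage genes 10 rose and 3 fell (10 and 3 adjusted over the list alone).

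The melanocytic list had an adjusted camera p of 0.0342, or adjusted p = 0.0811 with an estimated correlation, and its median of 1.02 was 0.72 without TYR and TRPM1, which held at most a few counts per library in DMSO. Of 15 neural crest and SOX10-associated genes 13 rose and 2 fell, with the same counts adjusted over the list alone; the receptor ERBB3 rose by 1.12 ± 0.057 and SOX10 by 0.45 ± 0.056 (list adjusted p = 0.00113; adjusted p = 0.179 with an estimated correlation). The dedifferentiated and invasive melanoma list went down, with 11 of 15 members lower and 3 higher (11 and 3 adjusted over the list alone). EGFR changed by -1.77 ± 0.057 and FOSL1 by -3.80 ± 0.06, while the AP-1 factor JUN rose against the list by 4.98 ± 0.047 (list adjusted p = 0.00439; adjusted p = 0.125 with an estimated correlation). The ERK and cell cycle calls held both ways, at adjusted p = 1.0e-15 and 5.7e-20, and adjusted p = 0.00176 and 0.01 with an estimated correlation. Of 15 p53 targets 11 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.00126, and 0.0359 with an estimated correlation). Further from these lists, the fatty acid receptor CD36 rose by 7.31 ± 0.17 and PRUNE2 by 6.82 ± 0.092, and the hyaluronan-binding protein CEMIP changed by -7.20 ± 0.09. The mitochondrial share of counts was 1.18% ± 0.042 in DMSO and 2.53% ± 0.196 under vemurafenib (SD, n = 3), and all 13 mitochondrial mRNAs rose (median 0.68). In total 8154 of 27453 genes passed, 5073 higher and 3081 lower.

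**Figure D1:**
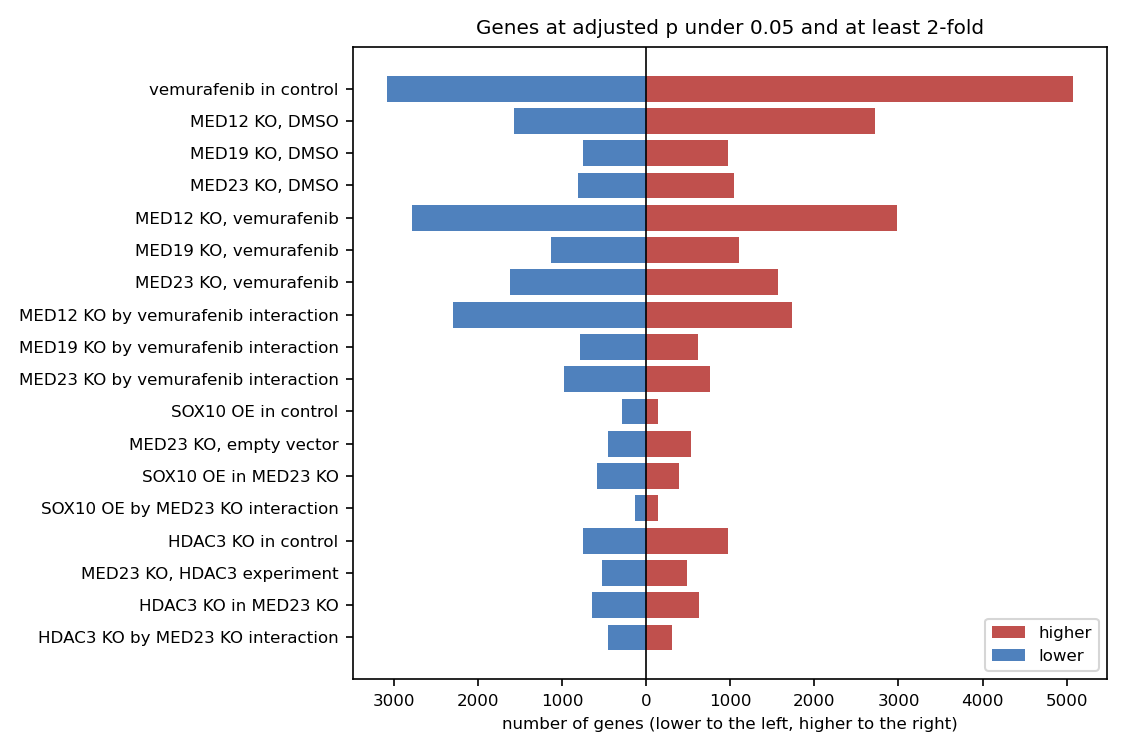
Number of genes (horizontal axis) that were higher (red, right) or lower (blue, left) in each of the 18 comparisons (vertical axis) at an adjusted p under 0.05 and at least 2-fold. Vemurafenib in control cells gave 8154 genes, MED12 knockout 4291 in DMSO and 5772 under the drug, and SOX10 overexpression in control cells 429.

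The MED12 comparison asked what loss of the kinase module subunit changes without the drug. All 17 interferon response genes rose at least 2-fold (17 adjusted over the list alone; median 4.67). The antiviral enzyme RSAD2 went from 0.157 ± 0.0597 CPM in control cells to 108 ± 37.5 with guide 1 and 115 ± 49.3 with guide 2 (mean ± SD, n = 3; 9.45 ± 0.36, adjusted p = 1.1e-27), and IFI44L rose by 7.92 ± 0.25. Neural crest and SOX10-associated genes went down: 12 of 15 fell and 2 rose (12 and 2 adjusted over the list alone; median -2.34), among them SOX10 (-2.68 ± 0.047, adjusted p = 8.5e-42), ERBB3 (-3.95 ± 0.05), the neurotrophin receptor NGFR (-2.95 ± 0.042) and the retinoid receptor RXRG (-5.40 ± 0.11). Of 22 YAP/TEAD targets 18 rose and 2 fell (18 and 2 adjusted over the list alone), led by CCN2 (3.07 ± 0.058). EGFR rose by 1.99 ± 0.043, adjusted p = 8.7e-38 and SOX9 by 2.58 ± 0.094, while SPRY4 changed by -2.47 ± 0.039 and MITF by -0.23 ± 0.03, adjusted p = 4.6e-09.

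By camera the interferon list had adjusted p = 6.9e-15, but adjusted p = 0.0722 with an estimated correlation. The neural crest and YAP/TEAD calls held both ways (adjusted p = 1.0e-07 and 4.5e-07; adjusted p = 0.0425 for each with an estimated correlation). 19 of 21 cell cycle genes fell and 1 rose (19 and 1 adjusted over the list alone), by a median of only -0.39 (adjusted p = 1.1e-07; adjusted p = 0.096 with an estimated correlation), with MKI67 at -0.66 ± 0.035. Lipid synthesis genes went the same way, with 14 of 16 lower and 2 higher (14 and 2 adjusted over the list alone; adjusted p = 7.1e-06, and 0.0425 with an estimated correlation), led by fatty acid synthase, FASN (-1.17 ± 0.037). The lowest values belonged to HAPLN1, a matrix link protein (-5.52 ± 0.052), and to the integrin ITGA9 (-5.44 ± 0.11). TNNT2 and BASP1 were also among the highest, but the 3 control libraries held only 7 and 12 counts of them in all. In total 4291 genes passed, 2720 higher and 1571 lower.

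Loss of MED19, measured with the same question, moved fewer genes. Of 15 neural crest and SOX10-associated genes 11 fell and 3 rose (11 and 3 adjusted over the list alone): SOX10 changed by -0.70 ± 0.047, adjusted p = 1.3e-17, ERBB3 by -1.27 ± 0.048 and RXRG by -2.64 ± 0.095. MITF changed by -0.83 ± 0.031, adjusted p = 9.6e-28, and EGFR rose by 1.43 ± 0.043, adjusted p = 3.1e-31. Of 15 dedifferentiated and invasive genes 9 rose and 2 fell (9 and 3 adjusted over the list alone), with SOX9 at 1.66 ± 0.095. All 16 lipid synthesis genes fell (16 adjusted over the list alone), with FASN at -0.73 ± 0.037 and SCD, a fatty acid desaturase, at -0.76 ± 0.026. The lipid call held both ways (adjusted p = 5.5e-11; adjusted p = 0.00345 with an estimated correlation), whereas the neural crest and dedifferentiated calls (adjusted p = 6.8e-06 and 9.8e-04) were lost, each with adjusted p = 0.073 with an estimated correlation. Of the genes with the largest changes, the scaffold protein SH3RF2 rose by 4.33 ± 0.18, NAV3 by 3.90 ± 0.11 and the interferon-induced gene OASL by 3.68 ± 0.26, while the activin antagonist FST changed by -2.95 ± 0.055. RN7SL2 and RN7SL4P were also among the lowest (-2.94 ± 0.47 and -2.91 ± 0.44), but these genes have near-identical copies, so their counts are uncertain. 1729 genes passed, 976 higher and 753 lower.

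In MED23 knockout cells the neural crest and SOX10-associated list fell and the dedifferentiated and invasive list rose. 12 of 15 neural crest genes fell and 2 rose (12 and 2 adjusted over the list alone; median -1.69), with SOX10 at -1.43 ± 0.047, adjusted p = 5.8e-30, ERBB3 at -1.69 ± 0.048, NGFR at -0.97 ± 0.041 and RXRG at -3.90 ± 0.1. 12 of 15 dedifferentiated and invasive genes rose and 3 fell (12 and 3 adjusted over the list alone), with SOX9 at 3.10 ± 0.095, EGFR at 2.48 ± 0.044, adjusted p = 1.1e-40 and the EGFR-family ligand NRG1 at 1.18 ± 0.11. Extracellular matrix and TGF-beta targets rose too (12 of 17 higher and 2 lower, 12 and 2 adjusted over the list alone), among them the collagens COL5A1 (2.41 ± 0.033) and COL1A1 (1.79 ± 0.069). The immediate early factors EGR1 and EGR3 changed by -3.67 ± 0.087 and -2.67 ± 0.089, in a list of 14 of which 8 fell and 2 rose (8 and 2 adjusted over the list alone). MITF rose by only 0.11 ± 0.031, adjusted p = 0.00445, and MKI67, at 0.02 ± 0.036, adjusted p = 0.757, did not pass. The microtubule protein MAP2 rose by 4.87 ± 0.12 and the retinoic acid-induced receptor GPRC5C by 4.41 ± 0.13, while DCT had 1035 counts over the 3 control libraries and 26 and 25 over those of the guides.

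The neural crest, dedifferentiated and matrix calls held both ways (adjusted p = 3.1e-11, 1.0e-07 and 1.0e-07; adjusted p = 0.0106, 0.00392 and 0.00381 with an estimated correlation). The immediate early call did not (adjusted p = 0.00739; adjusted p = 0.131 with an estimated correlation). 1863 genes passed in MED23 knockout cells, 1049 higher and 814 lower. Whether the 3 subunits change the same genes was asked by counting overlaps. MED12 and MED19 knockouts shared 844 higher and 534 lower genes, against 96.7 and 43.1 for independent lists. MED12 and MED23 shared 829 and 594 (103.9 and 46.6), and MED19 and MED23 shared 522 and 376 (37.3 and 22.3). A total of 490 genes were higher and 332 lower in all 3 knockouts. These comparisons use the same 3 control libraries, so part of the excess may come from shared controls. In 5 simulations of unchanged groups edgeR called 0 genes per knockout and so 0 shared ones, which does not measure this part.

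**Figure D2:**
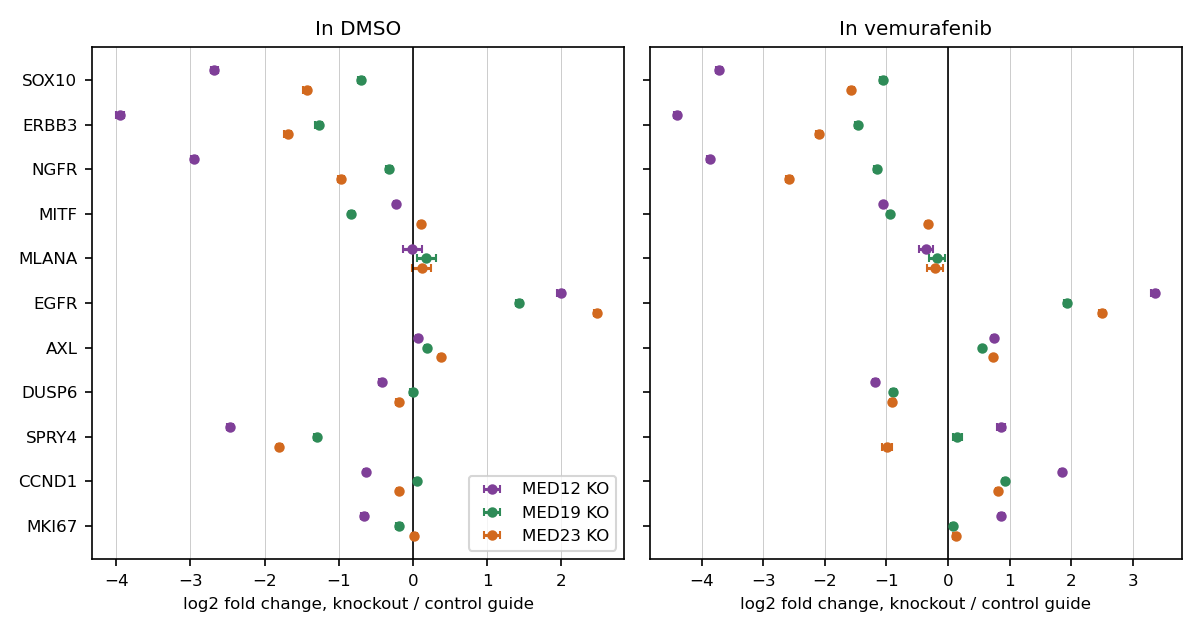
Log2 fold change against the control guide (horizontal axis, points with SE bars) of 11 genes chosen beforehand (vertical axis) in MED12, MED19 and MED23 knockout cells in DMSO (left) and under vemurafenib (right). SOX10 and ERBB3 lie below 0 and EGFR above 0 in each of the 3 knockouts under both treatments.

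The knockouts were next compared under vemurafenib, to see how cells lacking a subunit differ while the drug is present. Under the drug, melanocytic genes were lower in each knockout: 11 of 16 fell with MED12 loss, 11 with MED19 loss and 10 with MED23 loss, 3 rose in each, and the counts were the same adjusted over the list alone. DCT changed by -7.35 ± 0.08, -3.70 ± 0.068 and -5.43 ± 0.074 in that order, and MITF by -1.05 ± 0.029, -0.95 ± 0.029 and -0.33 ± 0.03. The call held both ways for each subunit (adjusted p = 0.0105, 0.00206 and 6.3e-04; adjusted p = 0.0254, 0.018 and 0.0084 with an estimated correlation). Of 15 neural crest and SOX10-associated genes 13, 12 and 13 fell and 2, 2 and 1 rose (13, 12 and 13, and 2, 2 and 1, adjusted over the list alone; medians -2.91, -1.14 and -1.79), with adjusted p = 3.8e-09, 2.4e-08 and 4.0e-11, and adjusted p = 0.0254, 0.0313 and 0.0166 with an estimated correlation. SOX10 changed by -3.72 ± 0.048, -1.06 ± 0.047 and -1.57 ± 0.046, and EGFR by 3.35 ± 0.052, 1.93 ± 0.052 and 2.50 ± 0.052. Of 22 YAP/TEAD targets, 21, 16 and 17 rose and 1, 3 and 2 fell, again with the same counts adjusted over the list alone. IGFBP3, a binding protein of insulin-like growth factors, rose by 3.24 ± 0.083, 1.72 ± 0.088 and 2.73 ± 0.085, and CCN1, a matricellular protein, by 4.44 ± 0.059, 1.53 ± 0.054 and 2.32 ± 0.055 (list adjusted p = 1.0e-11, 7.2e-07 and 1.8e-07; adjusted p = 0.0115, 0.0313 and 0.0241 with an estimated correlation).

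Cell cycle genes were higher than in drug-treated control cells. All 21 rose in MED12 knockout cells (21 adjusted over the list alone; median 1.11), with MKI67 at 0.86 ± 0.039, adjusted p = 8.0e-25 and CCND1 at 1.84 ± 0.028, adjusted p = 4.9e-45, and the call held both ways (adjusted p = 2.8e-14; adjusted p = 0.0254 with an estimated correlation). In MED19 and MED23 knockout cells 15 and 19 of them rose and 2 fell in each, with medians of 0.27 and 0.39 and the same counts adjusted over the list alone. Those calls (adjusted p = 1.2e-04 and 1.3e-05) were lost with adjusted p = 0.316 and 0.194 with an estimated correlation. CCND1 stood at 0.92 ± 0.027 and 0.81 ± 0.027. MKI67 was at 0.12 ± 0.039, adjusted p = 0.0119 in MED23 knockout cells and did not pass with MED19 loss (0.08 ± 0.038, adjusted p = 0.1), where guide 2 alone gave -0.13. JUN was lower in each knockout (-3.24 ± 0.033, -1.99 ± 0.032 and -2.46 ± 0.033), as was the immediate early factor EGR3 (-4.10 ± 0.11, -1.59 ± 0.094 and -4.36 ± 0.13). In total 5772, 2227 and 3192 genes passed, of which 2979, 1097 and 1567 were higher.

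Whether a subunit's loss changes the drug response itself was tested by the interaction, the knockout effect under vemurafenib minus that in DMSO, where a no-overlap criterion between libraries could not be applied. With MED12 loss all 21 cell cycle interactions were positive, so these genes fell less than in control cells (21 adjusted over the list alone; median interaction 1.54), with CCND1 at 2.47 ± 0.036, adjusted p = 2.3e-44 and MKI67 at 1.52 ± 0.053, adjusted p = 3.7e-29. The same list had medians of 0.39 with MED19 loss and 0.36 with MED23 loss, with 19 and 19 positive and 1 negative member in each, and the same counts adjusted over the list alone. JUN, which the drug raised in control cells, had interactions of -4.98 ± 0.054, -2.75 ± 0.053 and -3.54 ± 0.053. IGFBP3 (4.59 ± 0.099 with MED12 and 4.25 ± 0.1 with MED23 loss) and LOXL4, a lysyl oxidase that crosslinks matrix (4.19 ± 0.042, 3.21 ± 0.042 and 3.80 ± 0.042), were among the highest, and the secreted protein CCN3 was among the lowest (-5.32 ± 0.054 with MED12 and -4.24 ± 0.054 with MED23 loss). Melanocytic interactions were negative in 8, 8 and 6 of 16 genes and positive in 0, 0 and 1 (8, 9 and 6 negative, and 0, 1 and 1 positive, adjusted over the list alone). SPRY4 had interactions of 3.32 ± 0.075, 1.46 ± 0.08 and 0.81 ± 0.096.

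The cell cycle interaction held both ways for MED12 (adjusted p = 1.0e-22; adjusted p = 0.00922 with an estimated correlation), but not for MED19 and MED23 (adjusted p = 8.2e-10 and 1.0e-08; adjusted p = 0.082 and 0.116 with an estimated correlation). For the melanocytic list the adjusted p was 0.00155, 0.00183 and 0.00718, and adjusted p = 0.00922, 0.0117 and 0.0546 with an estimated correlation, so the MED23 call was lost. Interactions passed for 4036 genes with MED12, 1408 with MED19 and 1744 with MED23 loss. Among 2778 expressed genes of the control response, the median ratio of the knockout's log2 response to that of control cells was 0.44 with MED12 loss (0.45 and 0.43 by guide), 0.78 with MED19 loss (0.73 and 0.83) and 0.79 with MED23 loss (0.81 and 0.78). The mitochondrial share of counts under vemurafenib, 2.53% in control cells, was 2.05% and 1.84% with the MED12 guides, and all 13 mitochondrial mRNAs had negative MED12 interactions (median -0.68).

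**Figure D3:**
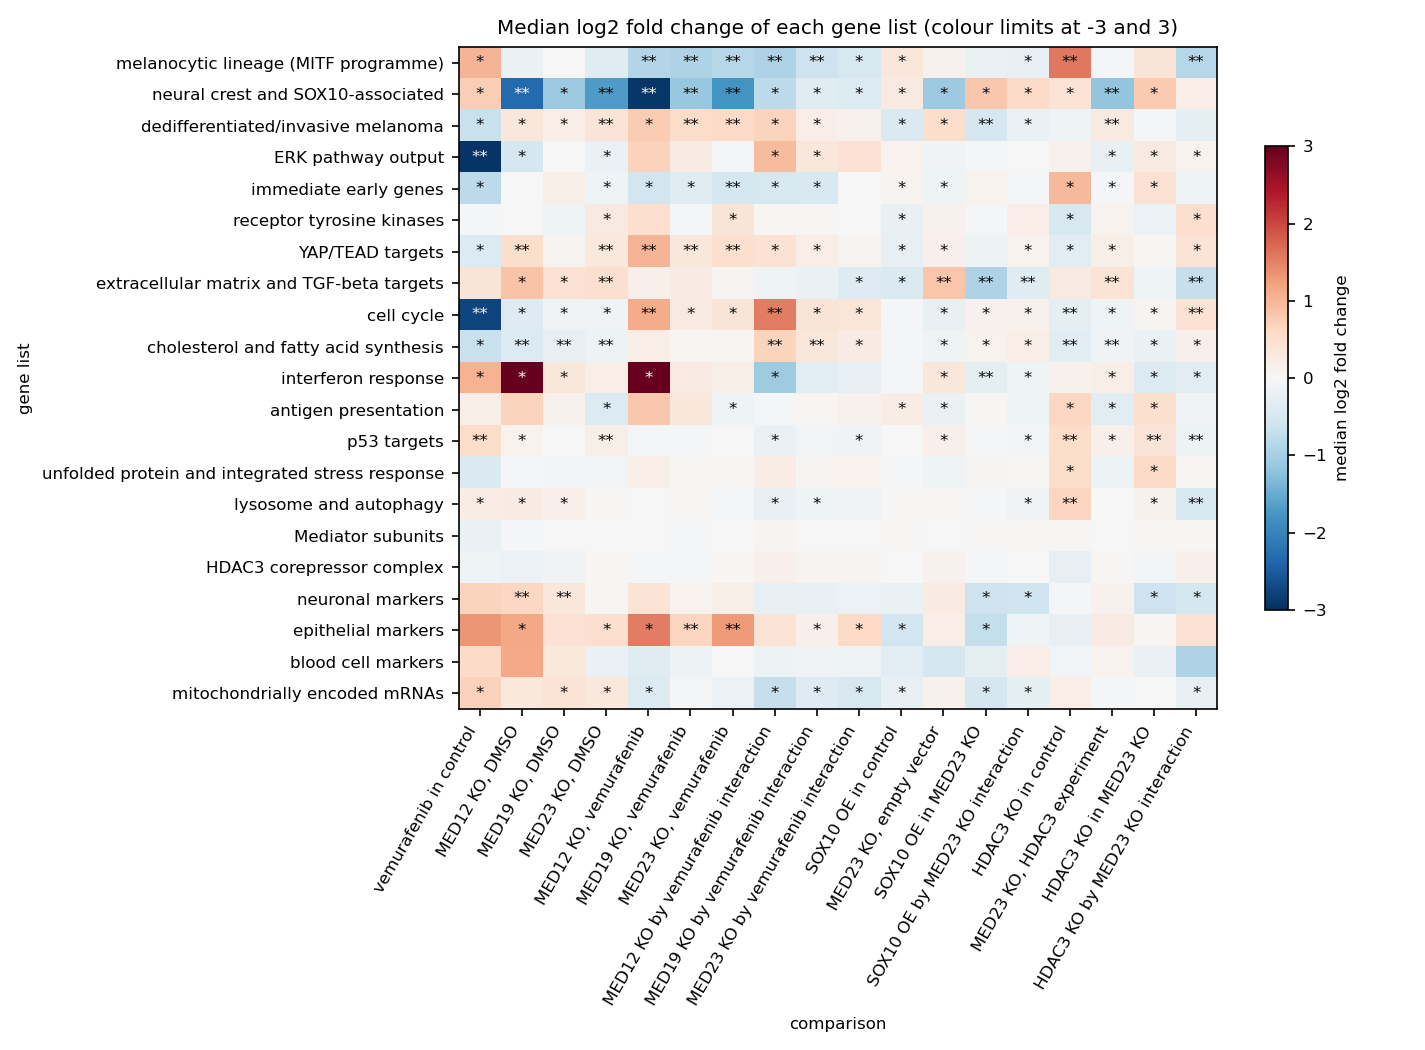
Median log2 fold change (colour) of each of 21 gene lists (vertical axis) in each of 18 comparisons (horizontal axis), with * where camera gave an adjusted p under 0.05 and ** where the call also held with an estimated correlation. The highest median belongs to interferon genes in MED12 knockout cells in DMSO (4.67) and the lowest to ERK pathway genes under vemurafenib in control cells (-2.94).

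SOX10 was overexpressed to ask what raising it does in control cells and in cells without MED23, where SOX10 mRNA was lower (-1.09 ± 0.03). In control cells DCT went from 2.09 ± 0.282 to 34.5 ± 1.73 CPM (mean ± SD, n = 3; 4.04 ± 0.089, adjusted p = 4.1e-24) and MITF from 57.5 ± 0.796 to 93.3 ± 2.71 (0.70 ± 0.043, adjusted p = 8.5e-14). Of 15 dedifferentiated and invasive genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), with EGFR at -0.76 ± 0.076. Of 15 neural crest genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with RXRG at 1.48 ± 0.047 and NGFR moving against the list at -0.80 ± 0.038. The list holds SOX10 itself, the gene that the vector carries, which is among the risen members. TRIM48, a ubiquitin ligase, was among the highest, with 21 counts over the 3 libraries of the empty vector and 962 with SOX10, and the largest falls belonged to the integrin ITGB4 (-2.52 ± 0.11) and the carboxypeptidase CPA4 (-2.49 ± 0.051). The calls for the dedifferentiated and neural crest lists (adjusted p = 4.3e-05 and 4.5e-04) were lost with adjusted p = 0.0703 and 0.1 with an estimated correlation. 429 of 18009 genes passed, 143 higher and 286 lower.

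In MED23 knockout cells the same vector changed more genes, 976, of which 385 were higher and 591 lower. Measured SOX10 mRNA also rose more with the vector in these cells than in control cells, as given above. Since these counts may or may not hold reads from the vector, it is not known whether the 2 backgrounds had equal overexpression. DCT had 16 counts over 3 libraries with the empty vector and 344 with SOX10, and TRIM48 26 and 965. 10 of 15 neural crest genes rose and 2 fell (11 and 2 adjusted over the list alone), with ERBB3 at 1.33 ± 0.033 and RXRG at 2.47 ± 0.082. SOX10 itself is again among the risen genes of this list. 12 of 15 dedifferentiated and invasive genes fell and 1 rose (13 and 1 adjusted over the list alone), with EGFR at -1.88 ± 0.051, and 13 of 15 matrix genes fell and 1 rose (13 and 1 adjusted over the list alone), with fibronectin, FN1, at -1.87 ± 0.037. The dedifferentiated and matrix calls held both ways (adjusted p = 9.8e-07 and 1.5e-07; adjusted p = 0.0352 and 0.00556 with an estimated correlation), and the neural crest call did not (adjusted p = 2.9e-06; adjusted p = 0.0697 with an estimated correlation). MITF behaved differently from control cells: it went from 65.1 ± 2.44 to 54.6 ± 4 CPM (-0.25 ± 0.044, adjusted p = 2.4e-05), and its interaction was -0.95 ± 0.062, adjusted p = 1.5e-12. The mitochondrial share of counts was 1.81% with the empty vector and 1.28% with SOX10 in these cells, and all 13 mitochondrial mRNAs fell (median -0.50).

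Interactions between SOX10 and MED23 loss passed for 280 genes, or 167 by the DESeq2 test. The measured rises of SOX10 mRNA were unequal, and whether they include the vector is not known. The interactions therefore cannot be read as different responses to the same rise of SOX10, nor as responses to different rises. ERBB3 (1.13 ± 0.046, adjusted p = 3.6e-17), the adhesion molecule CDH19 (1.42 ± 0.06) and CD200 (2.44 ± 0.21) rose more in MED23 knockout cells. The growth factor BMP4 (-2.58 ± 0.21, adjusted p = 1.7e-10), the pentraxin NPTX2 (-2.47 ± 0.11) and EGFR (-1.12 ± 0.094) fell more. 9 of 15 neural crest interactions were positive and 2 negative (9 and 2 adjusted over the list alone, list adjusted p = 1.2e-06, and adjusted p = 0.0542 with an estimated correlation). This list, too, was tested with SOX10 as a member. 8 of 15 matrix interactions were negative and 1 positive (8 and 1 adjusted over the list alone; adjusted p = 4.5e-06, and 0.0161 with an estimated correlation), with TGFBI, a TGF-beta-induced matrix protein, at -1.48 ± 0.047.

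HDAC3 was knocked out to ask what its loss does with and without MED23. In control cells DCT went from 1.21 ± 0.284 to 180 ± 5.21 CPM (mean ± SD, n = 3; 7.22 ± 0.12, adjusted p = 2.8e-21), the cytokine IL24 from 52.4 ± 3.83 to 1350 ± 58.4 (4.69 ± 0.057) and MITF from 58.3 ± 1.56 to 185 ± 10.3 (1.66 ± 0.054, adjusted p = 1.7e-16). 7 of 13 melanocytic genes rose and 1 fell (7 and 1 adjusted over the list alone), with the melanosome protein PMEL at 3.71 ± 0.17 (list adjusted p = 7.1e-05; adjusted p = 0.0144 with an estimated correlation). 13 of 15 lysosome and autophagy genes rose (13 adjusted over the list alone), with the protease CTSL at 2.19 ± 0.041 and the autophagy receptor SQSTM1 at 1.33 ± 0.046, and 14 of 15 p53 targets rose (14 adjusted over the list alone), with the cell cycle inhibitor CDKN1A at 1.46 ± 0.046 and the cytokine GDF15 at 1.36 ± 0.14; none of either list fell. Both calls held both ways (adjusted p = 3.6e-09 and 1.3e-07; adjusted p = 0.00743 and 0.00621 with an estimated correlation). 16 of 21 cell cycle genes fell and none rose (17 adjusted over the list alone; median -0.28; adjusted p = 6.3e-06, and 0.0144 with an estimated correlation). NGFR rose by 1.49 ± 0.053, EGFR changed by -1.18 ± 0.096, and SOX10 stood at 0.07 ± 0.051, adjusted p = 0.307, which did not pass. 1732 of 21139 genes passed, 978 higher and 754 lower.

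With MED23 already lost, HDAC3 knockout changed 1274 genes, 626 higher and 648 lower. Here SOX10 rose (0.78 ± 0.052, adjusted p = 5.5e-11), as did ERBB3 (0.86 ± 0.048) and CCND1 (0.86 ± 0.038), and 10 of 15 neural crest genes rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 1.7e-04, and adjusted p = 0.0546 with an estimated correlation). EGFR changed by -1.63 ± 0.086, adjusted p = 1.0e-12, and SOX9 by -3.52 ± 0.23, while DCT had 15 counts over 3 libraries of MED23 knockout and 551 with both knockouts, and IL24 rose by 4.91 ± 0.06. MITF, in contrast to control cells, went from 62.3 ± 2.37 to 53.2 ± 3.48 CPM (-0.23 ± 0.054, adjusted p = 0.00209), an interaction of -1.89 ± 0.076, adjusted p = 8.2e-14. The interaction list of melanocytic genes was negative in 8 of 13 members and positive in none (9 adjusted over the list alone; adjusted p = 7.1e-06, and 0.00593 with an estimated correlation), with PMEL at -3.31 ± 0.29. The lysosome interactions were negative in 13 of 15 members (14 adjusted over the list alone; adjusted p = 2.5e-11, and 0.00405 with an estimated correlation), with CTSL at -1.72 ± 0.056. The cell cycle interactions were positive in 19 of 21 (20 adjusted over the list alone; median 0.43; adjusted p = 2.6e-13, and 0.00291 with an estimated correlation). CCN3 (-3.38 ± 0.08) and the amino acid transporter SLC7A8 (-3.56 ± 0.17) were among the lowest interactions and the keratin KRT14 (2.34 ± 0.15) the highest, and 751 interactions passed. The melanocytic, lysosome and cell cycle interactions ran opposite to the effect of HDAC3 loss in control cells. They were not tested apart from a smaller response in general, as 482 expressed genes called in control cells kept a median share of 0.56. HDAC3 mRNA also fell less in MED23 knockout cells, as given above.

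**Figure D4:**
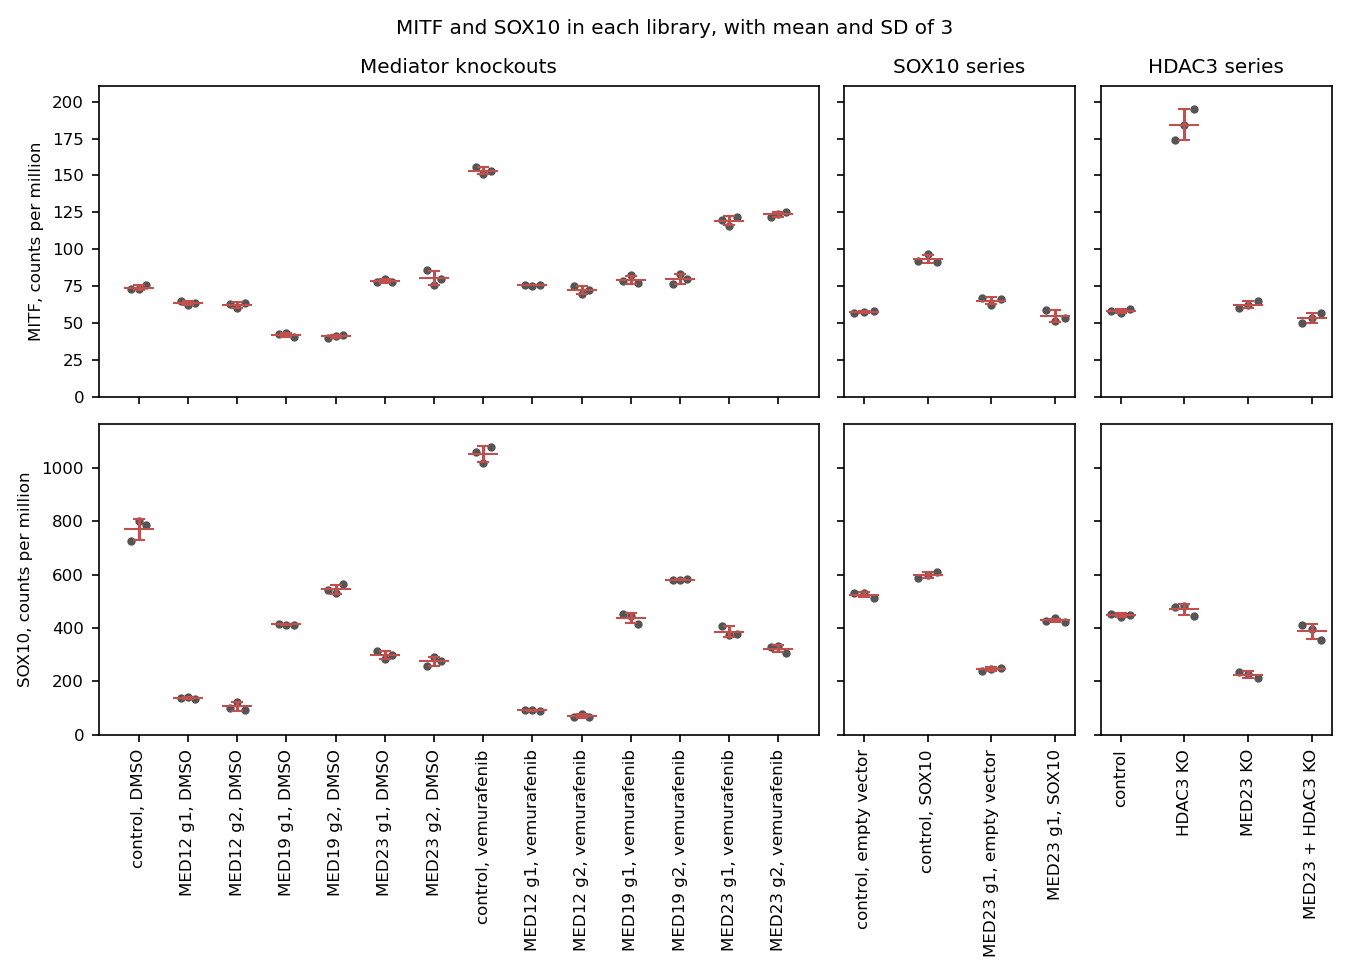
MITF (top) and SOX10 (bottom) in CPM (vertical axis) in each library (grey points), with mean and SD of 3 (red), for every group of the 3 experiments (horizontal axis; g marks the guide). MITF means are 93.3 with SOX10 overexpression and 185 with HDAC3 knockout in control cells, and 54.6 and 53.2 with the same changes in MED23 knockout cells.

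MED23 knockout was measured in each of the 3 experiments, which share no library. Genes lower in the first included RXRG and SOX10, and these were at -3.02 ± 0.077 and -1.09 ± 0.03 in the SOX10 experiment and at -3.26 ± 0.082 and -0.99 ± 0.052 in the HDAC3 experiment. EGFR was at 2.46 ± 0.055 and 2.10 ± 0.086 and MAP2 at 4.08 ± 0.18 and 5.13 ± 0.26. Across genes, which are not independent replicates, the log2 fold changes of the first experiment had Pearson's r of 0.861 and Spearman's rho of 0.753 with the SOX10 experiment (18003 genes) and 0.773 and 0.658 with the HDAC3 experiment (21105 genes), and the last pair had 0.819 and 0.703 (17954 genes). Of the genes that passed in the first experiment and were tested in the others, 87.6% passed an adjusted p of 0.05 with the same sign in the SOX10 experiment and 74.6% in the HDAC3 experiment; 0 and 5 passed with the opposite sign. With the 2-fold minimum, 992 and 1007 genes passed in these experiments.

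The last question was whether genes that change on MED23 loss move back when SOX10 is raised or HDAC3 is lost. The 814 genes lower and 1049 genes higher in MED23 knockout cells of the first experiment were followed in the others. Under SOX10 overexpression in MED23 knockout cells, 391 of 568 tested genes of the lower list rose and 17 fell (median 0.86), and 446 of 541 of the higher list fell and 7 rose (median -1.13). Under HDAC3 knockout in MED23 knockout cells, 374 of 662 of the lower list rose and 47 fell (median 0.77), and 332 of 677 of the higher list fell and 44 rose (median -0.73). A named member of the lower list was RXRG (2.47 ± 0.082 with SOX10, 1.93 ± 0.086 with HDAC3 loss), and members of the higher list were EGFR (-1.88 ± 0.051 and -1.63 ± 0.086) and MAP2 (-2.59 ± 0.14 with SOX10). By camera the adjusted p = 4.1e-37 and 1.3e-41 under SOX10, and the adjusted p = 8.4e-22 and 3.0e-14 under HDAC3 loss (adjusted p = 7.1e-05, 1.7e-07, 1.8e-05 and 2.0e-06 with an estimated correlation). The same lists moved in the same directions in cells with MED23, with medians of 0.41 and -0.67 under SOX10 and 0.44 and -0.29 under HDAC3 loss. The difference between the backgrounds had medians of 0.46 and -0.44 under SOX10 (adjusted p = 1.1e-22 and 9.5e-17) and 0.33 and -0.46 under HDAC3 loss (adjusted p = 1.6e-05 and 1.1e-07). Under SOX10 the backgrounds also differed in how far measured SOX10 mRNA rose, with or without reads from the vector. Under HDAC3 loss, measured HDAC3 mRNA fell less in MED23 knockout cells than in control cells.

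**Figure D5:**
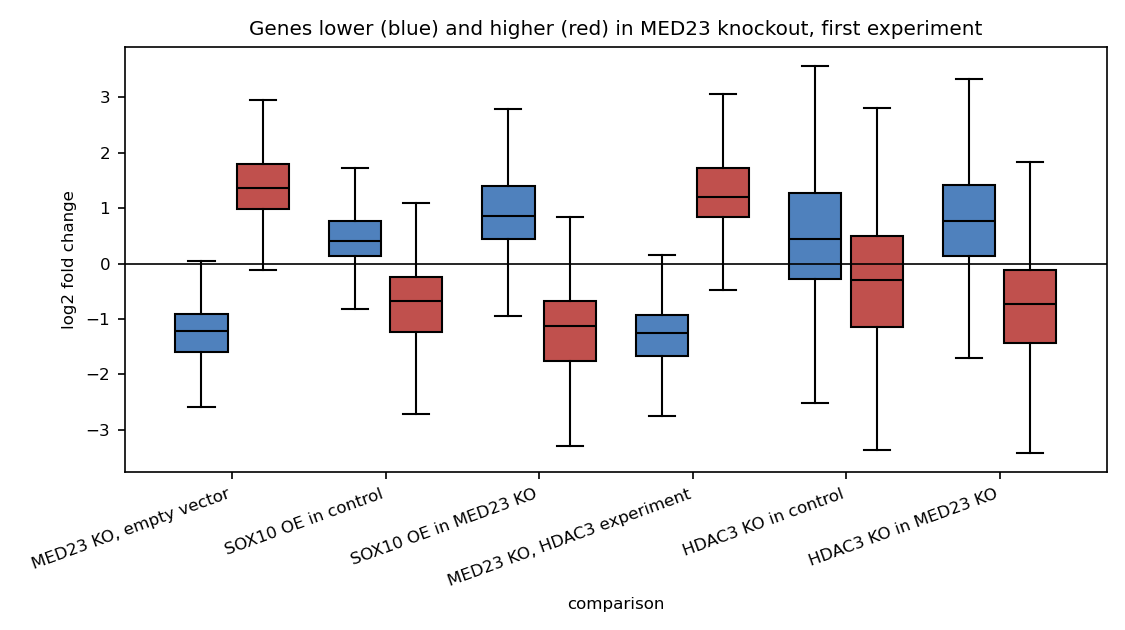
Log2 fold change (vertical axis) of genes lower (blue) and higher (red) in MED23 knockout cells of the first experiment, in 6 comparisons of the other experiments (horizontal axis); boxes span the quartiles, lines mark the median, whiskers reach 1.5 interquartile ranges and points beyond are not drawn. Medians are 0.86 and -1.13 under SOX10 overexpression and 0.77 and -0.73 under HDAC3 knockout in MED23 knockout cells.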

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

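The tests of other melanocytic genes, of splits with equal exchange, of single guides, of unexposed shares by size of the fall, of interferon genes against the other knockouts and of the unexposed share needed for the whole MED12 pattern were chosen only after the result was seen.

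A set of 8 results stood out because a gene chosen beforehand had effects of opposite sign in 2 backgrounds, with a tested difference. In MED12 knockout cells SPRY4 was lower in DMSO and higher under vemurafenib (-2.47 and 0.85; difference 3.32, adjusted p = 8.3e-37), as were CCND1 (-0.63 and 1.84; 2.47, adjusted p = 2.3e-44) and MKI67 (-0.66 and 0.86; 1.52, adjusted p = 3.7e-29). In MED23 knockout cells MITF went from 0.11 in DMSO to -0.33 under the drug (-0.44, adjusted p = 4.0e-12) and CCND1 from -0.19 to 0.81 (1.00, adjusted p = 4.4e-28). MITF rose by 0.70 with SOX10 overexpression in control cells and changed by -0.25 in MED23 knockout cells (-0.95, adjusted p = 1.5e-12). It rose by 1.66 with HDAC3 knockout and changed by -0.23 when MED23 was lost as well (-1.89, adjusted p = 8.2e-14), while SPRY4 had -0.30 and 0.38 (0.68, adjusted p = 4.5e-07). Each group had 3 libraries. Genes with opposite effects and a tested difference numbered 3344, 1714, 1778, 183 and 536 in the 5 interactions, of which 154, 37, 44, 1 and 12 changed 2-fold in both backgrounds.

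MITF's response to both SOX10 and HDAC3 loss was of opposite sign without MED23. Measured SOX10 mRNA rose more with the vector in MED23 knockout cells than in control cells, and HDAC3 mRNA fell less with HDAC3 knockout. The shares below do not take these differences into account. Thinning every library to 24.87 or 58.84 M counts left interactions of -0.95 (SE 0.064) and -1.90 (SE 0.078). MITF was far from the floor in every library, so this thinning could hardly have moved the values and adds little against depth. A weaker response of all genes was argued against: the median share of the control response kept in MED23 knockout cells was 0.99 with SOX10 and 0.56 with HDAC3 loss, whereas the share of MITF was -0.36 and -0.14; with HDAC3 loss many genes did respond less (quartiles 0.28 to 0.84), but weakening alone does not reverse a sign, and 23 of 482 genes lay at or below the share of MITF. Of the other melanocytic genes, 3 of 10 with SOX10 (median interaction -0.20) and 7 of 12 with HDAC3 loss (median -0.85) had negative interactions past the threshold and none a positive one (camera p = 0.0131 and 2.2e-05; 0.0321 and 0.00207 with an estimated correlation). Loss of MED23 stays open as an explanation with no test of its own, and it does not keep MITF from rising in general, since vemurafenib raised MITF by 1.05 in control cells with a MED23 interaction of -0.44; clonal differences were not tested and stay open as well, with 1 MED23 knockout per experiment.

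The vemurafenib response was smaller in MED12 knockout cells, with 0.44 of the control response kept. Genes already moved by the knockout were argued against as the whole explanation, since 926 genes that it moved by under 0.25 log2 in DMSO kept a median of 0.47 (quartiles 0.36 to 0.58). RNA from cells not reached by the drug would need a share of 40.4%, and 28 lowered genes, with 2 SE, fell to under 20.2% of their DMSO level, which such a share does not allow; DUSP6 fell to 8.09%. With 2 SE, 8 lowered genes fell to under 10%, which a share above 10% does not allow. A share below that cannot be told apart from a weaker response. Worked out by size of the fall, the 272 and 130 genes that fell by 2 to 3 and by over 3 log2 in control cells gave medians of 33.7% and 28.9% (quartiles 23.1 to 35.9 for the last). The 10 most lowered genes gave 9.9%, but single genes of these 10 lay between -1.1% and 76.3%, too far apart for the bound set beforehand to decide. Of the ERK pathway genes, 16 that fell in control cells kept a median of 0.59 of that response, from 0.19 to 1.96. DUSP6 fell more than in control cells (-3.63 ± 0.031), whereas ETV4 (-3.63 ± 0.035) and SPRY4 (-3.24 ± 0.04) fell less. The response was thus not weaker for every gene of the pathway. A weaker drug response without MED12 may explain the pattern in part, as a hypothesis.

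All 17 interferon genes were higher in MED12 knockout cells. A single guide was argued against, since the lower of the guides' list medians was 4.60. Low values in the control libraries were argued against for the list as a whole, since the same controls gave list medians of at most 0.33 in the MED19 and MED23 knockouts, although single interferon genes rose there as well, with OASL, outside the list, at 3.68 and 2.34. Blood cell markers, which immune cells would bring, had 3 higher and 3 lower of 9 (adjusted p = 0.803), which decides nothing. The call needs the preset correlation (adjusted p = 0.0722 with an estimated one), and whether loss of MED12 or an infection or stress of these populations may raise the genes was not tested.

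Other splits of the same libraries were counted for each comparison, fitted on those libraries alone with both guides as 1 group, so that real counts differ from those in the report. With 84 splits of 3 controls against 6 knockout libraries, only the real split gave as many genes, a share under 0.05. This held for MED12, MED19 and MED23 in DMSO (1 each, with 3949, 1393 and 1616 genes, highest other 0, 76 and 0). It also held under vemurafenib (1 each, with 5663, 2000 and 2637, highest other 0, 45 and 0). Other splits mix control and knockout libraries, which widens the spread within each group and lowers their counts. Libraries of 1 guide may share a culture, so a chance difference between cell populations is not excluded. The highest other splits called 2090, 2956, 2829 and 3081 genes at an unadjusted p under 0.05 where edgeR's count was 0, and for MED19 they set guide 1 against the rest. Among 60 drawn splits, with the real one, 2 were as large for the interactions of MED12 (4210 genes, highest other 4710), MED19 (1268, highest other 2422) and HDAC3 with MED23 (751, highest other 926), 3 for MED23 with the drug (1610, highest other 2903) and 7 for SOX10 with MED23 (280, highest other 2040). Each other split as large exchanged unequal numbers of labels in the 2 arms, which turns a main effect into a difference, so these splits show a structure of the samples and measure no chance, and their share decides for none of the 5 interactions whether chance can be excluded. The splits that exchanged as many labels in both arms (23, 19, 29, 22 and 21 in that order) called at most 1 gene by edgeR for MED23 with the drug and 0 for the others, with at most 3219, 2468, 923, 3171 and 762 genes at an unadjusted p under 0.05. They decide no more, since they too mix groups that differ by main effects, which widens the spread within each group.

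Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. Their values were 7372 genes for vemurafenib, 373 and 911 for SOX10 in control and MED23 knockout cells, 925 and 994 for MED23 knockout in the SOX10 and HDAC3 experiments, and 1661 and 1141 for HDAC3 in control and MED23 knockout cells, 1 split as large in each. The highest other was 0 by edgeR in each, with 126, 458, 597, 244, 1391, 458 and 549 genes at an unadjusted p under 0.05 in that order. Median shifts of genes lower in MED23 knockout cells were 0.88 with SOX10 and 0.78 with HDAC3 loss (highest other 0.31 and 0.28), and of higher genes 1.16 and 0.75 in size (highest other 0.39 and 0.28), again 1 split as large in each.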

How the results depend on the processing

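All tests in this part were planned before the results were seen.

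Each of the 18 counts of called genes stayed within 1.5 times its value with DESeq2 size factors, a replicate block, no low-count filter, only the groups compared and each replicate left out, and with each guide alone where there were 2. With the DESeq2 test the exception was SOX10 with MED23, where 167 genes were called instead of 280; the cause was not tested. Without the fold minimum, which admits smaller changes by construction, counts rose to 18161 for vemurafenib, to 15072, 11133 and 10122 for MED12, MED19 and MED23 in DMSO, to 17064, 12009 and 12982 under vemurafenib and to 13462, 8943 and 9545 for their interactions. They rose to 4069, 7822, 7543 and 2644 for SOX10 in control cells, MED23 with the empty vector, SOX10 in MED23 knockout cells and their interaction. For HDAC3 in control cells, MED23 in that experiment, HDAC3 in MED23 knockout cells and their interaction they rose to 8891, 5131, 8033 and 4333. Shared genes of MED12 with MED19, MED12 with MED23 and MED19 with MED23 rose to 9124, 7945 and 7188.

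Of 378 list tests 188 passed with the preset correlation, 55 with an estimated one, all 55 of them among the 188, and 187 with a replicate block. For HDAC3 knockout in MED23 knockout cells, where every pair of the same replicate number went together, the block gave 1267 genes instead of 1274. In the rest of that experiment, where most pairs did, it gave 1737 genes instead of 1732 for HDAC3 in control cells. For MED23 knockout it gave 1023 instead of 1007, and for the interaction 769 instead of 751. Pearson's r of MED23 fold changes between experiments was 0.229, 0.210 and 0.190 (Mediator with SOX10, Mediator with HDAC3 and SOX10 with HDAC3 experiment) without the low-count filter, which adds genes with few counts. The medians of genes that change on MED23 loss lay between 0.85 and 0.91 (lower) and between -1.19 and -1.11 (higher) under SOX10 without 1 replicate, and between 0.72 and 0.79 and between -0.76 and -0.72 under HDAC3 loss. Lists made with no fold minimum had medians of 0.15 and -0.20 under SOX10 and 0.11 and -0.17 under HDAC3 loss, with the same directions and side of the threshold.

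Among 17540 alternatives for named genes, 2 reversed. MKI67 in MED19 knockout cells under vemurafenib was -0.13 with guide 2 alone, with no test of the cause. CXCL10 in the MED12 interaction turned to 3.45 without replicate 3 of the drug-treated control, against -3.13 to -2.19 without each other replicate, but these values measure no change, since the control groups held 10 and 22 counts of CXCL10 in all and that replicate held all 22. A further 57 changed sign with neither value past the threshold. Leaving out 1 replicate ended 201 gene calls and added 37. DESeq2 size factors, the DESeq2 test, no low-count filter, only the groups compared and the replicate block moved the median of expressed genes by between -0.048 and 0.042 log2. Single guides and left-out replicates are not part of this range. Depth limits genes with a few counts per library, such as TYR and TRPM1.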

Other observations

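The likeness of SOX10 overexpression and HDAC3 knockout was chosen only after the results were seen, and has no test of its own.

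In MED23 knockout cells the log2 fold changes of SOX10 overexpression and of HDAC3 knockout had a Pearson r of 0.457 and a Spearman rho of 0.345 over 17954 genes. Of the called genes 162 were higher and 208 lower in both, against 9.4 and 18.5 for independent lists, and 25 were opposite. In control cells r was 0.308. Genes lower and higher in MED23 knockout cells had medians of 0.27 (adjusted p = 0.316) and 0.94 (adjusted p = 0.00151) under vemurafenib in control cells, where all genes had 0.11; this comparison shares its DMSO control libraries with the choice of the genes.

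The melanocytic list in DMSO had 5 higher and 7 lower genes of 16 with MED12 loss, 2 and 2 with MED19 loss and 3 and 7 with MED23 loss (adjusted p = 0.803, 0.891 and 0.278). The medians were -0.19, -0.01 and -0.36, and -0.19, -0.06 and -0.36 without TYR and TRPM1. The median, the mean and the test differed in sign in 41 of 378 list tests, of which 1 passed: the MED19 interaction of the dedifferentiated list (median 0.21, mean -0.01, up, adjusted p = 0.0326; 0.232 with an estimated correlation).

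Lists not described in the report are given as counts of members higher and lower at an adjusted p under 0.05, with no fold minimum (camera adjusted p; value with an estimated correlation). With HDAC3 loss, receptor tyrosine kinases had 1 and 14 of 20 (6.0e-05; 0.0685), antigen presentation 12 and 0 of 16 (3.0e-06; 0.0685), stress response 8 and 3 of 13 (0.00287; 0.141) and the HDAC3 corepressor complex, with the knocked-out HDAC3 among its lower genes, 2 and 5 of 8 (0.108; 0.168). With MED12 loss in DMSO, neuronal markers had 8 and 2 of 11 (0.00617; 0.0425), epithelial markers 9 and 2 of 12 (0.0125; 0.0722) and Mediator subunits, MED12 among them, 10 and 11 of 33 (0.803; 0.837). Epithelial markers had 8 and 1 with MED19 loss under vemurafenib (0.00206; 0.0313) and 9 and 2 with MED23 loss (0.00518; 0.0352). Blood cell markers passed in none of the 18 comparisons (lowest adjusted p = 0.32).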
